A study of Cavia porcellus with 6 samples.

How the data were processed

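The series holds RNA-seq of the posterior sclera of guinea pigs (Cavia porcellus), from 3 right eyes of form-deprived animals (FDM) and 3 of the control group (NC), taken on day 28 of induction. Samples were placed in groups and numbered by their titles. As each group is made of right eyes only, each library was taken to come from a separate animal, and the labels name no batch, cage or sampling time. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. A method of messenger RNA selection or ribosomal RNA removal is not given in the sources used here.

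The deposited values are raw read counts per gene in a single table of 6 columns, whole numbers with column totals of 10377397 to 17534982. The submitters' processing notes name Trimmomatic, a read trimmer, STAR, an aligner, and HTSeq, a read counter, as tools of the authors, without their order. Versions, counting mode, strand setting, genome build and annotation are not given in the sources used here. Without a strand setting, reads of overlapping or antisense genes cannot be told apart, and members of families of close copies, such as the 70-kDa heat shock genes, may share or lose reads. No coordinates are printed, because the build is not named.

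The table listed 32193 genes, of which 9738 had no count in any library, and held no line of unassigned reads. Of its identifiers 31776 matched a gene of the reference table of assembly mCavPor4.1, used for names only, and 417 did not, 414 of these being transfer RNA genes. Identifiers without a symbol (15518) were used as the table gives them. Gene lists use human symbols matched without regard to case. Symbols of list members with no match, among them HSPA1A, HSPA1B and HSPA1L, were not analysed here.

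Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with matplotlib 3.10.9. Genes were filtered with filterByExpr at its defaults, which left 16348 genes, 2740 of them without a symbol. Libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test with robust estimation, group as the only term and Benjamini-Hochberg adjustment, a gene being called at an adjusted p below 0.05. CPM values are counts scaled by TMM library sizes, given as mean ± SD over 3 libraries. Log2 fold changes are FDM against NC, with a standard error taken as the absolute fold change over the square root of the F statistic. List levels and principal components use log2 CPM with a prior count of 2. The common biological coefficient of variation was 0.933. The SD beside a value measures the spread between the libraries of a group, each taken to come from a separate animal. The SE comes from the fitted model, which draws its variance partly from other genes. The SD and SE are the precision given here.

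Before the data were examined, 34 gene lists with 799 entries were fixed from textbook knowledge, of which 732 were in the table and 680 tested. They cover ER chaperones, the unfolded protein response, heat shock, collagens and their processing, proteoglycans, glycoproteins, matrix proteases, TGF-beta signalling, contractile genes, metabolism, cell cycle, immediate early genes, interferon, inflammation and NRF2 targets. Markers of fibroblasts, chondrocytes, retina, pigment epithelium, melanocytes, muscle, endothelium, Schwann cells, blood and immune cells, fat and epithelium complete them. The 33 lists with at least 5 tested members were tested with edgeR's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 33. The same lists were tested with an estimated correlation per list and with fry, whose directional p asks whether the genes of a list move, on balance, one way and whose mixed p asks whether they change in either direction.

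The genes named in the text follow a rule fixed before the data were examined. It takes the 10 genes of largest and 10 of smallest log2 fold change among those called, with a symbol, an average log2 CPM of at least 1 and no overlap of the groups. With fewer than 5 genes called in a direction, as here, the genes of smallest p that meet the other criteria fill the places. It adds members of each list among the 4 of smallest p and 25 genes of ER stress and matrix always. Some genes taken by the rule are left out of the text. Genes outside the rule are said to be chosen after their values were seen.

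Alternatives fixed beforehand were DESeq2, limma-voom with and without sample weights, RLE, upper-quartile and total-count scaling, no filter and a filter of 1 CPM in 3 libraries, non-robust estimation, the replicate number as a block, other thresholds and each library left out in turn. After seeing the data, fits without both libraries numbered 1, with muscle and photoreceptor list means as covariates, with genes detected in at least 5 libraries, with edgeR's newer quasi-likelihood form and with a shortened heat shock list were added. The tests were first tested on counts simulated from the means, totals and estimated dispersions of the 16348 genes with 200 genes changed. There edgeR recovered 5.97% of genes changed 4-fold, 53.7% of those changed 16-fold and 75.8% of those changed 64-fold, with 7 false calls among 97, over 15133 genes tested. With much lower dispersions it recovered 73.1%, 98.5% and 100%. Each simulated gene was drawn independently of the others.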

Results

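RNA sequencing measured gene expression in the posterior pole of the sclera, the collagen-rich outer coat of the eye, of guinea pigs, as read counts per gene. Form deprivation, in which an eye is covered so that it sees no sharp image, is a standard way of inducing axial myopia in this species. The study compared right eyes taken on day 28 of induction, 3 from form-deprived animals (FDM) and 3 from the control group (NC). The series title places the work in scleral endoplasmic reticulum (ER) stress and protein misfolding and also names quercetin, but none of the 6 libraries is labelled as treated with it. The FDM libraries 1, 2 and 3 held 12048216, 15025573 and 16181865 counts and the NC libraries 10377397, 13811527 and 17534982.

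The libraries numbered 1 in each group stood apart from the rest. FDM 1 had counts for 12783 genes and NC 1 for 14416, against 17689 to 20591 in the other 4 libraries. Of 8061 genes with a mean of over 300 counts, 223 had none in FDM 1 and 96 had none in NC 1, while the other 4 libraries lacked 0 to 4 of them. The first principal component, with 48.1% of the variance, set FDM 1 apart and the second, with 29.2%, set NC 1 apart. Across genes, log2 CPM correlated with Pearson r of 0.682 to 0.822 in the 6 pairs within a group and 0.644 to 0.887 in the 9 pairs between groups. Genes are not independent replicates, and these r values describe the libraries only.

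The comparison of FDM with NC asks which scleral genes differ after form deprivation, with the protein folding genes of the series title in front. Genes for cytosolic heat shock proteins, which refold damaged proteins, rose as a group in FDM, by a median log2 fold change of 1.44 with all 23 measured members positive. Immediate early genes, transcription factors and their partners that are switched on within minutes of a stimulus, rose by a median of 1.51 with 23 of 24 positive. ER chaperones and the genes of ER-associated degradation rose less, by a median of 0.41 with 27 of 30 positive. Without FDM 3 the medians of these 3 groups were 0.61, 0.89 and 0.25. In the heat shock group FDM 2 and NC 3 both averaged 7.50 log2 CPM, against 9.47 in FDM 3. Skeletal muscle genes rose and photoreceptor genes fell as groups, and both varied widely between libraries of a single group. In the order given, the groups were called by edgeR's camera at adjusted p of 4.34e-15, 1.65e-22, 2.38e-05, 1.45e-16 and 3.21e-08. These calls use its preset inter-gene correlation of 0.01. With an estimated correlation the adjusted p of edgeR's camera was 0.367 for the first 3 groups, 0.512 for muscle and 0.746 for photoreceptors, and none of the 33 lists tested was called. With the preset correlation 13 lists were called, 11 higher and 2 lower in FDM. That count was 22 without NC 1, and the lists called higher numbered 7 without FDM 1, 19 without NC 1 and 5 without NC 2.

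No single gene passed. Of 16348 genes tested, 0 had an adjusted p below 0.05 in edgeR's quasi-likelihood test, the smallest being 0.999999. At an unadjusted p below 0.05 the test gave 156 genes, 108 higher and 48 lower, where 817.4 are expected by chance. Scaling by total count alone, which moved the median log2 fold change of all genes from 0.02 to -0.23, gave 50 higher and 130 lower at that level. Leaving out FDM 1, FDM 2, FDM 3, NC 2 or NC 3 gave 240, 246, 536, 84 and 338 genes. DESeq2, run on 22455 genes without edgeR's filter, called 24 genes at adjusted p below 0.05, 19 higher and 5 lower. Of these 12 had counts in a single library. On the 16348 genes limma-voom called 0. All 3 FDM libraries lay above all 3 NC libraries for 447 genes (2.73%) and below them for 460 (2.81%), where chance gives 5% in each direction and 10% in both. An exact permutation test of a single gene with 3 against 3 libraries cannot give a two-sided p under 0.1. Without both libraries numbered 1, a choice made after seeing the data, edgeR's test again gave 0 genes.

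Because no gene passed in either direction, the genes below are those of smallest p, and none of them passed edgeR's test. Without FDM 3 the log2 fold change of 34 of the 102 genes named in the text shrank by more than 1.5 times and that of 5 changed sign. These numbers were 10 and 4 without FDM 1, 1 and 2 without FDM 2, 5 and 1 without NC 1, 17 and 2 without NC 2 and 6 and 3 without NC 3. Hspa6, an inducible member of the 70-kDa heat shock protein family, averaged 4094 ± 6155 CPM (SD, n = 3) in FDM and 3.81 ± 1.86 in NC, a log2 fold change of 10.06 ± 1.80 (SE). Its FDM libraries held 849, 239 and 11193 CPM, and without FDM 3 the log2 fold change was 7.10. Hsph1, a nucleotide exchange factor for that family, averaged 2084 ± 2927 against 97.2 ± 35.4 CPM (SD, n = 3), and Zfand2a, a zinc finger gene induced by heat and arsenite, 240.6 ± 301 against 23.6 ± 5.72. The log2 fold changes of these genes were 4.42 ± 1.18 and 3.35 ± 0.91 (SE), and 1.96 and 1.45 without FDM 3. The AP-1 and stress transcription factor genes Fos, Jun and Atf3 had log2 fold changes of 4.35 ± 0.87, 3.53 ± 0.92 and 3.88 ± 0.96 (SE), and 3.58, 1.71 and 2.53 without FDM 3. The prostaglandin E receptor gene Ptger1 had 3.21 ± 0.81, Pxdc1 2.04 ± 0.49, the bZIP repressor gene Nfil3 1.76 ± 0.52 and the cell cycle inhibitor gene Cdkn1a 1.44 ± 0.40. DESeq2 gave Hspa6 an adjusted p of 1.73e-13, Fos 0.00092, Hsph1 0.0215 and Atf3 0.0387. Read sharing between close copies of the 70-kDa heat shock genes could not be checked, so the level of Hspa6 is uncertain. Chosen after their values were seen, the protein-coding genes LOC100717205 and LOC100729464, which carry no symbol, had log2 fold changes of 5.49 ± 1.26 and 5.73 ± 1.37 (SE), and 3.48 and 3.29 without FDM 3. These genes took 1.43% and 1.57% of all counts of FDM 3.

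Among genes with lower values in FDM, Rgr, an opsin of the pigment epithelium and Müller glia, averaged 31.9 ± 5.74 CPM in FDM and 116.2 ± 64.5 in NC (SD, n = 3), a log2 fold change of -1.86 ± 0.54 (SE). Its NC libraries held 156.2, 150.7 and 41.8 CPM, and FDM 3 held 38.5. Retinal markers varied widely between libraries of a single group, so values of retinal and neural genes cannot be assigned to the sclera itself. The neurofilament gene Nefh had -1.77 ± 0.52 and Hif3a, an alpha subunit gene of the hypoxia-inducible factors, -1.86 ± 0.58. Hif3a lay at 8.48 to 9.17 CPM in FDM and 21.3 to 43.0 CPM in NC. The stanniocalcin gene Stc2 had -2.38 ± 0.86 and the gamma-glutamyltransferase family gene Ggt7 -1.21 ± 0.40. The coiled-coil genes Ccdc85c and Ccdc24 had -1.62 ± 0.58 (-0.98 without NC 2) and -2.0 ± 0.76, and the uncharacterised CUNH3orf70 -1.34 ± 0.51. Slc10a4, a gene of synaptic vesicles, had -4.61 ± 1.76 on 0, 4 and 15 counts in the FDM libraries against 90, 164 and 239 in NC, and DESeq2 gave it an adjusted p of 0.0421.

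ER chaperones and ER-associated degradation rose as a list, with 0 of 30 members past edgeR's test over all genes and 0 adjusted over the list alone. The list was not called with an estimated correlation (adjusted p = 0.367 in edgeR's camera). For 7 of them all FDM libraries lay above all NC libraries. Hspa5, the main ER chaperone, averaged 734.7 ± 397 CPM in FDM and 216.0 ± 70.6 in NC (SD, n = 3), a log2 fold change of 1.77 ± 0.58 (SE). Manf, a secreted ER stress protein, had 1.71 ± 0.58 and Dnajc3, an Hspa5 co-chaperone, 1.23 ± 0.61. Hsp90b1 and Calr, which encode abundant chaperones of the ER lumen, had 0.41 ± 0.52 and 0.42 ± 0.56, and the disulfide isomerase gene Pdia4 0.63 ± 0.40. Without FDM 3 Hsp90b1 and Pdia4 had 0.215 and 0.36, and without NC 2 Calr had 0.14. The list of unfolded protein response sensors and the PERK-ATF4-CHOP branch also rose in edgeR's camera (adjusted p = 0.0282), by a median of 0.33 with 14 of 21 members positive, 0 of them past the test over all genes and 0 adjusted over the list alone. Its adjusted p with an estimated correlation was 0.367. The list shares Atf3 with the immediate early list. Atf3 had a log2 fold change of 3.88 ± 0.96 (SE), and 2.53 without FDM 3, and the list was not tested without this gene. Ddit3, which encodes the pro-apoptotic factor CHOP, averaged 46.7 ± 25.4 against 14.3 ± 4.63 CPM (SD, n = 3), a log2 fold change of 1.71 ± 0.60 (SE), and Xbp1 had 0.98 ± 0.42. The eIF2-alpha phosphatase subunit gene Ppp1r15a had 1.76 ± 0.85, and 0.24 without FDM 3. The transcription factor gene Atf4 had 0.07 ± 0.50. The sensor genes Atf6, Eif2ak3 (PERK) and Ern1 (IRE1-alpha) had -0.64 ± 0.41, 0.73 ± 0.76 and -0.29 ± 0.76, and Eif2ak3 had -0.68 without FDM 3. The camera call of the second list ended without FDM 1 (adjusted p = 0.131), FDM 3 (0.101), NC 2 (0.162) or NC 3 (0.0687), and was 0.00385 and 0.00957 without FDM 2 and NC 1. The median of 0.33 was 0.19, 0.16 and 0.24 without FDM 1, 2 and 3 and 0.10, 0.17 and 0.09 without NC 1, 2 and 3. The first list kept an adjusted p between 3.55e-06 and 0.00929 with any single library left out, and its median was 0.25 without FDM 3. With total-count scaling the medians of the first and second list were 0.18 and 0.03, where the median of all genes was -0.23.

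**Figure D1:**
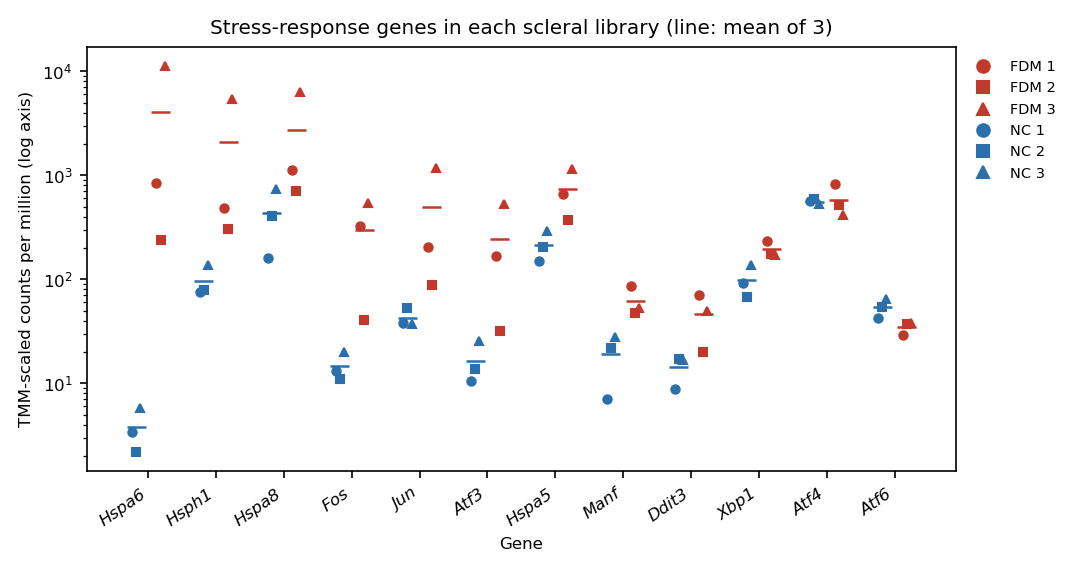
TMM-scaled CPM (log axis) of 12 stress-response genes in the 3 FDM and 3 NC libraries, with the marker shape giving the replicate number and lines the mean of each group. Hspa6 lay at 239 to 11193 CPM in FDM and 2.18 to 5.83 in NC, Hspa5 at 375 to 1161 and 150 to 291, and Atf4 at 419 to 821 and 527 to 588.

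The cytosolic heat shock list averaged 7.65, 7.50 and 9.47 log2 CPM in FDM 1, 2 and 3 and 6.33, 6.85 and 7.50 in NC 1, 2 and 3. Of its 23 members 0 passed edgeR's test over all genes and 0 adjusted over the list alone. Ahsa1, a co-chaperone of HSP90, averaged 229.9 ± 119 CPM in FDM and 82.2 ± 39.4 in NC (SD, n = 3), a log2 fold change of 1.48 ± 0.54 (SE), and 0.90 without FDM 3. The constitutive chaperone gene Hspa8 had 2.66 ± 1.02, and 1.0 without FDM 3. Dnajb1, a co-chaperone of the 70-kDa family, had 6.40 ± 2.28, which rested on 274 CPM in FDM 3 against 1.97 and 3.03 in FDM 1 and FDM 2, and 1.15 without FDM 3. Leaving out FDM 3 brought the list's median to 0.61, with an adjusted p of 6.82e-05 in edgeR's camera. Over all single libraries left out the adjusted p ran from 1.41e-19 to 6.82e-05 at the preset correlation, while with an estimated correlation it was 0.367 and the list was not called.

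Immediate early genes averaged 6.43, 5.18 and 7.36 log2 CPM in FDM 1, 2 and 3 and 4.42, 4.16 and 5.07 in NC 1, 2 and 3. Over all genes 0 of 24 passed edgeR's test, and adjusted over the list alone 7 passed, all higher. These were Fos, Atf3, Jun and Ier2 and, named after their values were seen, Fosb, Egr1 and Dusp1, with list-wide edgeR adjusted p of 0.0197 for Fos and 0.0345 to 0.0422 for the others. Fos, which forms the AP-1 dimer with Jun, averaged 301.1 ± 249 CPM in FDM and 14.7 ± 4.84 in NC (SD, n = 3). Jun averaged 493.3 ± 602 against 42.8 ± 8.43 and Atf3 242.0 ± 257 against 16.5 ± 7.83 CPM (SD, n = 3). Ier2 had a log2 fold change of 1.43 ± 0.43, Fosb 6.01 ± 1.74, the zinc finger factor gene Egr1 3.62 ± 1.12 and the MAP kinase phosphatase gene Dusp1 2.72 ± 0.87 (SE), the last 3 having 4.65, 2.11 and 1.08 without FDM 3. The count of 7 was 5 without FDM 1, 10 without FDM 2 and 0 without FDM 3 or any NC library. It was 1 with total-count scaling, 8 in DESeq2, 11 in edgeR's newer form, and 0 in limma-voom with or without weights, with the replicate number as a block, with muscle and photoreceptor list means as covariates and without both libraries numbered 1. The list's median was 0.89 without FDM 3, and its edgeR camera adjusted p stayed between 2.14e-36 and 1.20e-10 with any single library left out at the preset correlation, but was 0.367 with an estimated correlation.

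Inflammatory cytokines and NF-kB targets rose in edgeR's camera (adjusted p = 0.00213), by a median of 0.58 with 20 of 22 members positive and 0 past the test over all genes or adjusted over the list alone. The adjusted p was 0.367 with an estimated correlation. Il6 averaged 19.8 ± 18.8 CPM in FDM and 2.86 ± 1.63 in NC (SD, n = 3), a log2 fold change of 2.79 ± 1.13 (SE), and 1.75 without FDM 1. Lif, a cytokine of the same family, had 2.67 ± 1.72 and the alarmin gene Il33 1.15 ± 0.51 (0.69 without FDM 3). The interferon and antigen presentation list rose by a median of 0.43 with 15 of 22 positive and 0 past either adjustment (edgeR's camera, adjusted p = 0.0128, and 0.776 with an estimated correlation). Irf1 had 1.48 ± 0.47 and Irf7 0.88 ± 0.65 (0.42 without NC 2). Of the macrophage and dendritic cell markers, 12 of 17 were positive with a median of 0.17 and no call (adjusted p = 0.492 in edgeR's camera), and 0 passed either adjustment. Cd68, a lysosomal protein of macrophages, lay at 21.3 to 29.9 CPM in FDM and 6.71 to 9.01 in NC, a log2 fold change of 1.83 ± 0.61 (SE), and Cd83 had 0.98 ± 0.71 (0.64 without FDM 3). Without FDM 1 or NC 2 the adjusted p of the inflammatory list was 0.124 and 0.148, and without FDM 2, FDM 3 or NC 2 that of the interferon list was 0.0639, 0.101 and 0.756. The median of the inflammatory list was 0.14 without FDM 1, and that of the interferon list 0.25 without FDM 3 and 0.19 without NC 2. The macrophage list reached 0.00622, with a median of 0.73, without NC 1.

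Collagen genes as a list were not called. Their median log2 fold change was 0.46 with 15 of 23 positive, 0 past either adjustment and an adjusted p of 0.245 in edgeR's camera. Col1a1, the main fibrillar collagen of the sclera, averaged 19452 ± 11197 CPM in FDM and 13826 ± 15676 in NC (SD, n = 3), a difference smaller than the spread within either group. Its log2 fold change was 0.49 ± 1.2 (SE), and Col1a2 had 0.46 ± 1.06 and Col3a1 1.43 ± 0.91. Col5a2 had 1.18 ± 0.71, Col6a3 0.82 ± 0.52 and the cartilage collagen gene Col2a1 -1.26 ± 0.67 (-0.82 without FDM 1). Without FDM 3 Col3a1, Col5a2 and Col6a3 had 0.50, 0.24 and 0.36. Without NC 1, which had the highest Col1a1 at 31767 CPM, the list's adjusted p was 1.93e-04 and its median 0.80, while without FDM 3 these were 0.944 and -0.03. The list was also called higher in edgeR's camera with the muscle and photoreceptor covariates (5.13e-06, median 0.89) and without both libraries numbered 1 (3.86e-04, median 0.82), where its adjusted p with an estimated correlation was 0.577 and 0.71. Collagen processing and crosslinking enzymes rose by a median of 0.40 with 21 of 27 positive and 0 past either adjustment (edgeR's camera, adjusted p = 0.00113, and 0.746 with an estimated correlation). The galactosyltransferase gene Colgalt1 had 1.36 ± 0.53, the prolyl hydroxylase genes P3h1 and P4ha1 0.93 ± 0.39 and 1.40 ± 0.63, the procollagen protease gene Adamts14 1.19 ± 0.74 and the crosslinking enzyme gene Lox 0.82 ± 0.60. Colgalt1 had 0.62 and P4ha1 0.25 without FDM 3. The adjusted p of this list was 0.198 without FDM 3 and 0.375 without NC 2, with medians of 0.25 and 0.09, and the median was 0.74 without NC 1.

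Glycoproteins and elastic fibre genes rose by a median of 0.30 with 19 of 27 positive (edgeR's camera, adjusted p = 0.0094, and 0.776 with an estimated correlation). Matrix proteases and their inhibitors rose by a median of 0.34 with 16 of 22 positive (adjusted p = 0.0282 in edgeR's camera, and 0.746 with an estimated correlation). In both lists 0 members passed either adjustment. The tenascin gene Tnxb averaged 387.5 ± 185 against 135.5 ± 65.3 CPM (SD, n = 3), a log2 fold change of 1.52 ± 0.54 (SE), the fibronectin gene Fn1 had 1.30 ± 0.69, and Ccn1, a matrix protein induced by serum, had 2.79 ± 1.03. Without FDM 3 these 3 genes had 1.001, 0.35 and 1.04. The gelatinase gene Mmp2 had 0.57 ± 0.75 (0.15 without NC 2), Mmp14 0.30 ± 0.60 (-0.67 without FDM 3), Timp1 1.15 ± 1.01 (-0.37 without FDM 1) and Timp2 0.76 ± 0.62 (0.14 without FDM 3). The urokinase gene Plau had 1.63 ± 0.74 and the aggrecanase gene Adamts5 0.95 ± 0.47, and 0.50 and 0.52 without FDM 3. The glycoprotein call ended without FDM 1 (0.0636), FDM 3 (0.267) or NC 2 (0.801), and the protease call ended without FDM 1 (0.0834), FDM 3 (0.198) or NC 2 (0.756), all as adjusted p of edgeR's camera. The protease call also ended when only genes detected in at least 5 libraries were tested (0.0577), a filter added after seeing the data. The glycoprotein median was 0.03 without FDM 3, -0.08 without NC 2, 0.55 without FDM 2 and 0.88 without NC 1. The protease median was 0.03 without FDM 3, 0.15 without NC 2 and 0.51, 0.54, 0.60 and 0.56 without FDM 1, FDM 2, NC 1 and NC 3.

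Proteoglycans (median 0.49, 16 of 24 positive, adjusted p = 0.153), TGF-beta and BMP signalling (0.24, 26 of 34, 0.0896) and fibroblast and tenocyte markers (0.16, 10 of 17, 0.813) were not called by edgeR's camera. Myofibroblast and contractile genes had a median of -0.33 with 6 of 15 positive and no call (0.813), although camera gave the opposite sign, higher. Chondrocyte markers had a median of -0.54 with 3 of 11 positive (0.0515). In these 5 lists 0 members passed over all genes or adjusted over the list alone. The small leucine-rich proteoglycan genes Dcn, Lum and Bgn had log2 fold changes of 0.53 ± 0.91, 0.78 ± 0.74 and -0.27 ± 0.96 (SE), and Dcn and Lum had -0.54 and -0.46 without FDM 3. Spock2 had -1.66 ± 0.72 and the glypican gene Gpc1 0.83 ± 0.52 (0.43 without FDM 1). Tgfb1 had 0.56 ± 0.48 (0.28 without NC 2), Tgfb2 -0.16 ± 0.49, the betaglycan gene Tgfbr3 1.12 ± 0.60 and the BMP antagonist gene Chrd 1.95 ± 0.77, the last 2 having 0.21 and 1.28 without FDM 3. Acta2, the smooth muscle actin of myofibroblasts, had -0.78 ± 0.80 (-0.23 without NC 1). Des and Tpm2, which skeletal muscle also expresses, had 1.60 ± 0.85 and 1.44 ± 0.92, and Tpm2 had 0.89 without FDM 1. Des and Tpm2 had their 2 highest values in FDM 1 and FDM 2, which also had the highest muscle marker levels. The fibroblast marker Clec3b had 0.74 ± 0.67 (0.31 without FDM 1). Without NC 1 the adjusted p was 5.13e-05 for proteoglycans, 0.00788 for TGF-beta signalling and 7.78e-04 for fibroblast markers, all higher, and the last was 0.0316 and lower without NC 2. Calls also arose for proteoglycans without FDM 2 (3.52e-04) and TGF-beta signalling without FDM 1 (0.00914) or NC 3 (0.0377), all higher, and for chondrocyte markers, lower, without FDM 2 (0.00728) or NC 1 (0.0406). Proteoglycans, TGF-beta signalling and fibroblast markers were also called higher with the muscle and photoreceptor covariates (1.37e-06, 0.00517 and 3.15e-04) and without both libraries numbered 1 (0.00148, 6.93e-04 and 5.5e-04), though none of them with an estimated correlation. Contractile genes were called lower without FDM 1 (0.0323) or NC 2 (0.00575) and higher without NC 1 (0.0148).

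Among metabolic and growth lists, nuclear-encoded oxidative phosphorylation genes rose by a median of 0.19 with 19 of 21 positive (edgeR's camera, adjusted p = 0.0253, and 0.875 with an estimated correlation). The members measured were of complexes I and II and the ATP synthase, and Ndufa2, of complex I, had a log2 fold change of 1.12 ± 0.57 (SE), and 0.66 without FDM 1. Scaling by total count alone gave a list median of -0.12, where the median of all genes was -0.23, and an adjusted p of 0.129 in edgeR's camera. The call also ended without FDM 1 (0.98), FDM 2 (0.148) or NC 1 (0.389), with medians of 0.095, 0.07 and -0.04, and the median was 0.33 without FDM 3 and 0.30 without NC 3. The list turned lower and was not called with the muscle and photoreceptor covariates (median -0.19, adjusted p = 0.264) or without both libraries numbered 1 (median -0.22, adjusted p = 0.16). FDM 1 and FDM 2 were also highest, and NC 1 lowest, in skeletal muscle markers. Hypoxia and glycolysis genes had a median of -0.33 with 7 of 29 positive and no call (0.221). The vasodilator peptide gene Adm had 2.32 ± 0.75, the brain-type aldolase gene Aldoc -1.57 ± 0.85 (-0.87 without NC 2) and Hif1a -0.33 ± 0.48. Proteasome subunits (median 0.27, 25 of 30 positive, adjusted p = 0.0528), ribosomal proteins (0.14, 24 of 31, 0.221), cholesterol synthesis (-0.26, 8 of 22, 0.481), cell cycle (0.07, 15 of 28, 0.72) and NRF2 targets (0.05, 11 of 20, 0.93, with camera's sign lower) were not called. In all 7 lists 0 members passed over all genes or adjusted over the list alone. Psmd11 had 0.50 ± 0.41 (0.24 without NC 1) and the cholesterol synthesis gene Hmgcs1 -1.07 ± 0.55 (-0.68 without NC 3). The antioxidant genes Sod3 and Gsr had 1.14 ± 0.47 and -1.11 ± 0.65, and Gsr had -0.69 without FDM 1. Without NC 1 the adjusted p of edgeR's camera was 5.52e-10 for ribosomal proteins and 0.00601 for proteasome subunits, both higher, and 0.0403 for hypoxia genes, lower. Without FDM 3 the ribosomal and proteasome lists had 6.82e-05 and 1.51e-05, higher, without FDM 1 the ribosomal list had 0.0271, lower, and without NC 3 the hypoxia list had 0.0465, lower.

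Skeletal muscle markers averaged 10.97, 10.22 and 8.66 log2 CPM in FDM 1, 2 and 3 and 1.28, 9.28 and 10.01 in NC 1, 2 and 3, and all 28 had a positive log2 fold change with a median of 1.38. Acta1, skeletal muscle actin, was named after its values were seen. It was the most abundant gene of FDM 2 with 1.55% of its counts, and lay at 19.9 CPM in NC 1. Mybpc2, Actn3 and Tnnc2, of fast muscle fibres, had log2 fold changes of 2.50 ± 1.63, 2.10 ± 1.39 and 2.16 ± 1.5 (SE). Photoreceptor and retinal neuron markers averaged 0.80, 4.74 and 7.26 log2 CPM in FDM 1, 2 and 3 and 7.13, 8.42 and 3.46 in NC 1, 2 and 3, and all 26 had a negative log2 fold change with a median of -1.45. Snap25 had -1.55 ± 1.05 (-0.60 without NC 2) and the neurofilament gene Nefl -1.84 ± 0.74. Retinal pigment epithelium markers fell by a median of -0.69 with 8 of 11 negative (edgeR's camera, adjusted p = 0.0112, and 0.557 with an estimated correlation). Their members Rlbp1, a retinoid carrier, and Best1, a chloride channel, had -1.27 ± 0.59 and -1.34 ± 0.72, and Best1 had -0.74 without NC 1. In these 3 lists 0 members passed over all genes or adjusted over the list alone. Without both libraries numbered 1 the muscle list had an adjusted p of 0.887, the photoreceptor list 0.173 and the pigment epithelium list 0.0745 in edgeR's camera. With a single library left out the muscle and photoreceptor lists stayed called at the preset correlation, at an adjusted p of up to 4.51e-05 and 0.0348, but with an estimated correlation neither was called (0.512 and 0.746). The muscle median was 0.84 without FDM 1 or NC 1, and the photoreceptor median -0.96, -3.50 and -0.34 without FDM 1, FDM 3 and NC 2. The pigment epithelium call ended without FDM 2 (0.332) or NC 1 (0.228), and its median was -0.25 without FDM 1 and -0.30 without NC 1. With the muscle and photoreceptor covariates that call also ended (0.314), with a median of -0.29.

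With the muscle and photoreceptor list means of each library as covariates, added after seeing the data, the heat shock list had a median of 1.27, the immediate early list 1.49 and the ER chaperone list 0.43. Their adjusted p in edgeR's camera were 1.49e-20, 8.11e-32 and 3.82e-07, and 0.482 for all 3 with an estimated correlation. Without both libraries numbered 1 the medians were 1.54, 1.34 and 0.37. At the preset correlation edgeR's camera called 17 lists with the covariates, 16 higher and 1 lower, and 14 without both libraries numbered 1, 13 higher and 1 lower, and with an estimated correlation 0 in either fit. Of lists that the main fit did not call, macrophage markers were called higher in both fits (0.0246 and 7.38e-04), ribosomal proteins higher (0.00303) and Schwann cell markers lower (5.03e-04) with the covariates, and hypoxia genes lower (0.0141) without both libraries, beside the collagen and matrix lists given above. The UPR sensor list had a median of 0.08 with the covariates and an adjusted p of 0.0828 without both libraries numbered 1.

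**Figure D2:**
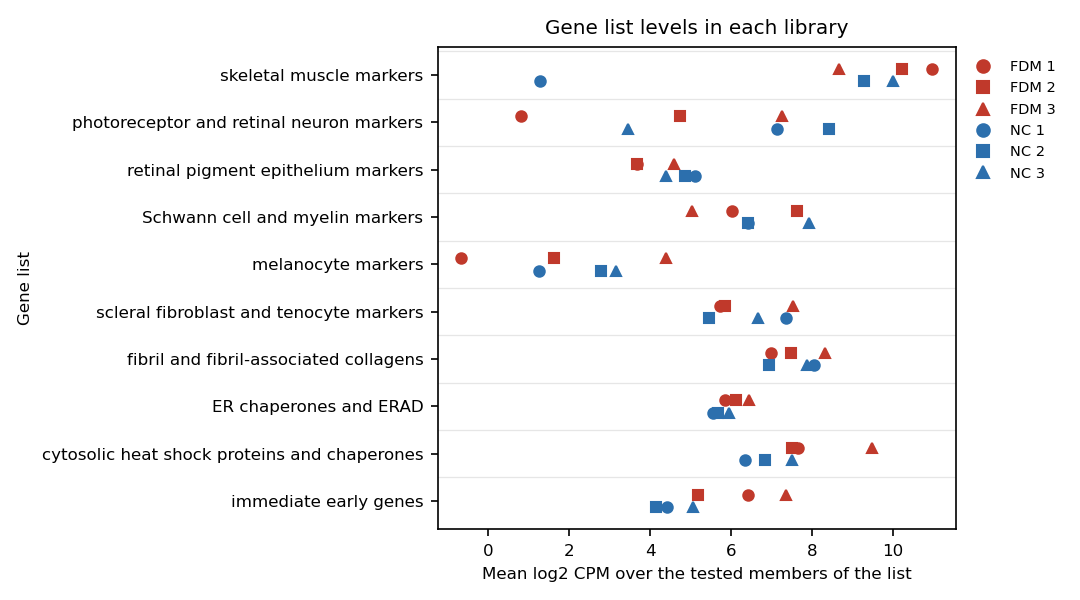
Mean log2 CPM over the tested members of 10 gene lists in each of the 6 libraries, with the colour giving the group and the marker shape the replicate number. Muscle markers ran from 1.28 in NC 1 to 10.97 in FDM 1 and photoreceptor markers from 0.80 in FDM 1 to 8.42 in NC 2, while ER chaperones ran from 5.56 to 6.44.

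Other cell types gave no call in edgeR's camera. Melanocyte markers had a median log2 fold change of 0.20 with 11 of 13 positive (adjusted p = 0.72, with camera's sign lower), endothelial markers 0.23 with 12 of 18 (0.4) and Schwann cell and myelin markers -0.21 with 6 of 16 (0.221). Neutrophil and mast cell markers had 0.06 with 3 of 6 positive (0.72), erythroid markers -0.74 with 1 of 5 (0.0528), adipocyte markers 0.37 with 7 of 13 (0.397) and epithelial markers 0.16 with 8 of 13 (0.813, with camera's sign lower). In these 7 lists 0 members passed over all genes or adjusted over the list alone. The endothelial diaphragm gene Plvap had 1.12 ± 0.59 (0.63 without FDM 1), the adipocyte protease gene Cfd 1.04 ± 0.64 (0.61 without NC 2) and the water channel gene Aqp5, of glands, -2.76 ± 1.5 (SE). Lymphocyte markers had fewer than 5 tested members and were not tested as a list. Left-out libraries brought the Schwann list to an adjusted p of 4.9e-05 without FDM 2 and 0.00586 without NC 2, the endothelial list to 0.0347 without FDM 3 and 0.0403 without NC 1, and the melanocyte, erythroid and adipocyte lists to 0.0247, 0.0236 and 0.0465 without FDM 3, FDM 1 and NC 3.

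**Figure D3:**
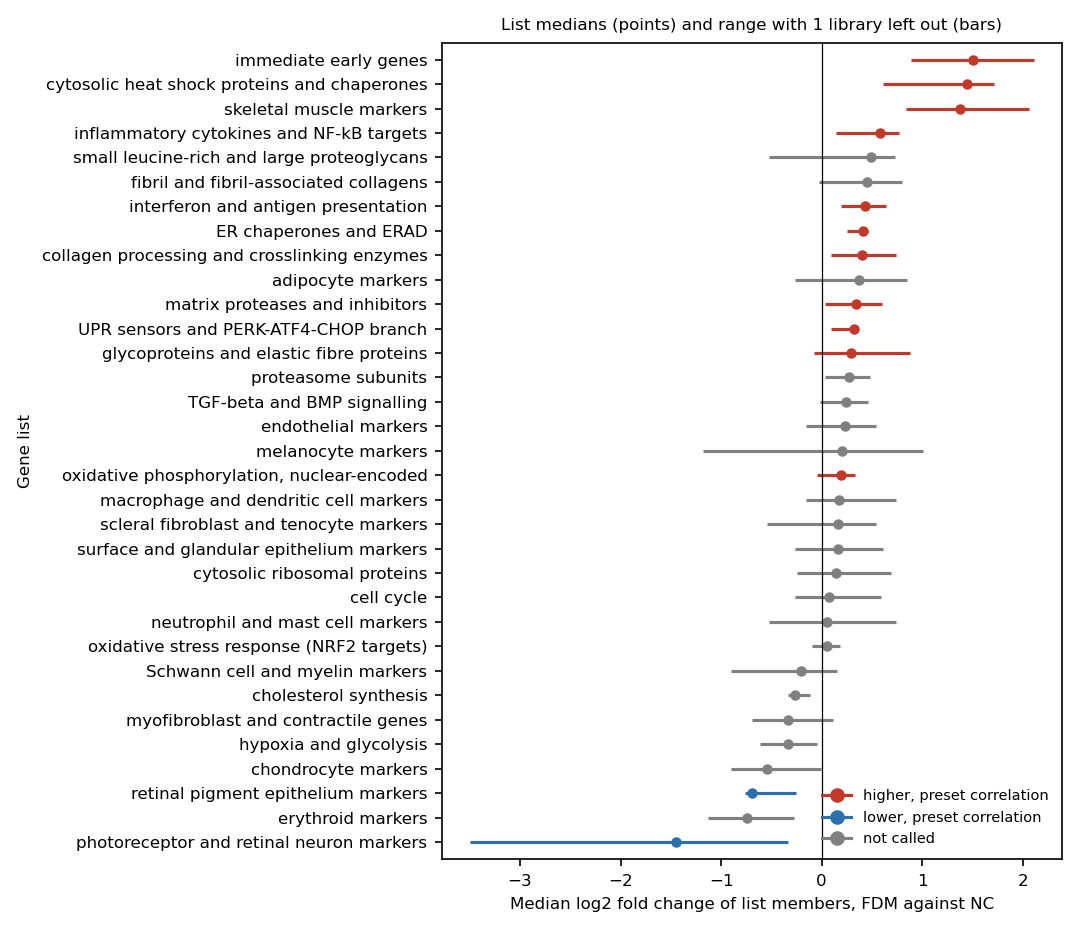
Median log2 fold change, FDM against NC, of the members of each of the 33 lists (points) with the range of that median when each of the 6 libraries is left out in turn (bars), coloured by the call of edgeR's camera with its preset correlation. The medians ran from -1.45 for photoreceptor markers to 1.51 for immediate early genes, and the heat shock bar reached down to 0.61.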

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

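The fits without both libraries numbered 1, with covariates, with genes detected in at least 5 libraries, with edgeR's newer form and with a shortened heat shock list were chosen after seeing the data. EdgeR's quasi-likelihood test called 0 genes in every setting run with it, over 14499 to 22455 genes tested, and limma-voom with and without weights called 0. The 156 genes at an unadjusted p below 0.05 became 84 (without NC 2) to 536 (without FDM 3), 367 with no filter, 335 in edgeR's newer form, 450 in limma-voom with weights and 486 in DESeq2. DESeq2 was run on 22455 genes without edgeR's filter. It called 24, 19 higher and 5 lower, of which 12 had counts in a single library. The threshold of unadjusted p below 0.05 with an absolute log2 fold change of at least 1 gave 150 genes, 104 higher and 46 lower. In the simulation edgeR made 97 calls at this size, but each gene was drawn independently of the others. In the real libraries the estimated correlation within the heat shock list was 0.433, and Hspa6 was not called at a log2 fold change of 10.06. The simulated recovery of large changes therefore cannot be carried over to these libraries. Even in the simulation edgeR recovered 5.97% of genes changed 4-fold, so a count of 0 does not exclude changes of that size.

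Of the 13 lists called, 11 higher and 2 lower, camera with an estimated correlation and fry called 0 in either direction. Their adjusted p were 0.367 and 0.575 for ER chaperones, UPR sensors and immediate early genes and 0.367 and 0.649 for heat shock. The smallest adjusted p over the 33 lists was 0.367 with an estimated correlation, 0.454 in fry and 0.877 in fry's mixed form. With a single library left out, camera called 10 (without NC 2) to 22 lists (without NC 1), 5 to 19 of them higher and 3 to 5 lower. Without both libraries numbered 1 it called 14 lists, 13 higher and 1 lower, and with the covariates 17, 16 higher and 1 lower, and with an estimated correlation 0 in either fit. UPR sensors had an adjusted p of 0.00385 to 0.162 with a library left out and 0.0828 without both libraries numbered 1. The direction of oxidative phosphorylation turned at an adjusted p of 0.16 without both libraries numbered 1 and 0.264 with the covariates. The muscle list turned to lower at 0.887 without both libraries numbered 1, although its median stayed at 0.23, and the photoreceptor list to higher at 0.726 with the covariates, which hold its own mean. Of the lists called in the main fit or after leaving out the library, those that turned with a library left out ran from 2.69e-08 to 0.801 for glycoproteins, 0.00575 to 0.508 for contractile genes, 5.52e-10 to 0.881 for ribosomal proteins and 7.78e-04 to 0.881 for fibroblast markers. Turns with no call in either fit were seen in 17 lists with a library left out and in 8 lists in other settings. The cause was not tested beyond the fewer libraries or added terms of these fits.

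The replicate number as a block, which left 2 residual degrees of freedom, gave 0 genes and 14 lists, 3 of them lower with chondrocyte markers at an adjusted p of 0.0298. Deviations of libraries with the same number correlated across genes at 0.0951, 0.0335 and -0.152, all under the bar of 0.1 set for pairing. With 3 libraries per group this cannot exclude that the numbers mark pairs or a shared batch. Both libraries numbered 1 detected few genes, 12783 in FDM 1 and 14416 in NC 1.

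None of the named genes passed edgeR's test, and the signs of these turned. Atf4 had a log2 fold change of -0.22 with total-count scaling, -0.0085 with no filter, -0.35 without both libraries numbered 1, -0.16 with covariates and -0.092 with limma-voom weights. Bgn had 0.30 with the block, 0.73 without both libraries numbered 1, 0.99 with covariates, and 0.23 and 0.25 with limma-voom without and with weights. Eif2ak3 had -0.029 and Tgfb2 0.038 with limma-voom weights, Ern1 had 0.086 and Tgfb2 0.094 without both libraries numbered 1, and Timp1 -0.0145 with covariates. Gfap had -6.21 with the block, -7.19 with limma-voom and -1.70 with its weights. With a library left out the log2 fold changes ran from -0.26 to 0.19 for Atf4, -0.68 to 1.15 for Eif2ak3, -1.53 to 0.19 for Ern1, -0.0069 to 1.997 for Col1a1, -0.23 to 1.625 for Col1a2, -0.54 to 1.37 for Dcn, -0.46 to 1.201 for Lum, -0.91 to 1.425 for Bgn, -0.67 to 0.66 for Mmp14, -0.37 to 1.74 for Timp1, -0.47 to 0.20 for Tgfb2, -0.60 to 0.14 for Hif1a, -8.84 to 1.38 for Gfap and -3.27 to 0.14 for Mbp. DESeq2 called 8 of the 102 named genes, Hspa6, Fos, Fosb, Atf3, Hsph1, Slc10a4, LOC100717205 and LOC100729464. All other settings left the sign of each of these 102 genes as it was.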

Other observations

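Tests chosen only after the result was seen are the handling test, both tests of form deprivation as the whole cause, the count share test, and the astrocyte and oligodendrocyte list. The fits with covariates and without both libraries numbered 1 were also added after seeing the data.

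Genes of astrocytes and oligodendrocytes, glial cells of the optic nerve, are in no fixed list as a group and differed between single libraries. Over 14 such genes, listed after the data were seen, the mean was 8.18 log2 CPM in FDM 2 and 1.88 and 2.38 in FDM 1 and FDM 3, and 5.51, 6.76 and 7.69 in NC 1, 2 and 3. Their median log2 fold change between the groups was -0.22 with 5 positive. Gfap, the filament of astrocytes, lay at 8624 CPM in FDM 2, 7.69 in FDM 1 and 0 in FDM 3, and at 574, 1472 and 3151 CPM in NC 1, 2 and 3. The myelin gene Mbp followed, with 3399 CPM in FDM 2, 302 in FDM 1 and 106 in FDM 3, and 875, 1284 and 3712 CPM in NC 1, 2 and 3. Of these genes 4 also stand in the fixed Schwann cell list.

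The heat shock and immediate early lists were higher in FDM. More skeletal muscle in the FDM libraries would leave list medians of 0 or lower once the muscle and photoreceptor means are taken out. These were then 1.27 and 1.49, with 1.49e-20 as the larger adjusted p of edgeR's camera for the 2 lists. The fit cannot decide on muscle, because it left 2 residual degrees of freedom and its muscle term rested mostly on NC 1. Muscle markers averaged 1.28 log2 CPM in NC 1 and 8.66 to 10.97 in the others, and kept a median of 0.32 in this fit. Photoreceptor markers were lower in FDM, so no excess of retina there was tested. Without both libraries numbered 1 the medians were 1.54 and 1.34 and the larger adjusted p 7.5e-13. Both medians thus stayed positive without these libraries. This fit cannot decide on few starting molecules, because it left 2 residual degrees of freedom and its difference rested mostly on FDM 3. FDM 2 lay close to NC 3, at 7.50 and 7.50 log2 CPM for heat shock and 5.18 and 5.07 for immediate early genes. Both values rest on camera's preset correlation, and with an estimated correlation the adjusted p was 0.482 and 0.71. Handling before freezing that differed between the groups could also raise early genes, and the median of 1.51 cannot be told apart from an effect of form deprivation, because no sampling time is in the labels. The 10 splits of the 6 libraries are too few for a share under 0.05, and the real split gave a -log10 p of 15.4 for heat shock (highest other 12.8), 23.3 for immediate early genes (18.5) and 5.44 for ER chaperones (2.87), the smallest p in 1 of 10 splits for each.

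Retinal and muscle genes differed strongly between libraries of a single group. The photoreceptor mean ranged over 6.45 log2 units in FDM and 4.96 in NC against a group difference of 2.07, a ratio of 2.4, which argues against form deprivation as the whole cause. For muscle the ranges were 2.31 and 8.73 against 3.10, a ratio of 0.745, which decides nothing. Members moved together over the 6 libraries, with a median correlation with the mean of the other members of 0.967 in the retinal and 0.976 in the muscle list, against 95th percentiles of 0.348 and 0.62 in 1000 random lists matched on expression. Uneven amounts of adjoining retina and extraocular muscle in the pieces of sclera are a candidate explanation of both.

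The libraries numbered 1 detected the fewest genes. Depth does not account for it, since at an equal total of 10377397 counts the lowest of the other 4 still detected 3205 more genes than NC 1, the higher of the pair. In those 2 libraries 2.66% and 2.62% of detected genes had 1 to 10 counts, at least 8.76 percentage points fewer than in the others, which is consistent with few starting molecules, each read many times. No biological explanation was tested, as a library of each group shows it.

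Over the whole comparison the 10 splits are too few for a share under 0.05. The real and the highest other count of genes were both 0, which any split matches, so these counts decide nothing. For lists, 6 of 10 splits gave as many, 13 in the real split and up to 19 in others. At an unadjusted p below 0.05 the real split gave 156 genes and the others 150 to 1233. The split with 1233, the largest of the 10, puts FDM 1, FDM 2 and NC 1 together, and the reason for its count was not tested. Genes whose groups do not overlap made up 5.55% in the real split and 5.64% to 18.9% in the others.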
